A study of Hermetia illucens with 24 samples.

How the data were processed

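RNA abundance was measured in larvae of the black soldier fly *Hermetia illucens*, an insect reared on organic waste. Per the labels, larvae 5 days old were placed on chicken feed with or without aflatoxin B1 (AFB1), a toxin of *Aspergillus* moulds, and were collected after 6, 24 and 72 h. Each library was made from total RNA of 2 pooled larvae and sequenced as pairs of 150 bp reads, per the labels' protocols. The protocols mention 5 pools per diet and time, and the table holds 4 libraries of each. The labels place the 24 libraries in 6 groups of 4, given by diet and time. The labels describe separate pools of larvae within a group, but not whether the pools came from separate rearing containers. The p-values of the gene tests thus rest on the spread between pools within groups. That spread was estimated from all 24 libraries together, not only from the groups compared. It includes the control libraries of 72 h, which were nearly identical and may be repeats of the same RNA.

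The deposited table holds raw read counts per gene, with 1 column per library. STAR is named in the submitters' processing notes. The counting tool, the genome build, the strand setting and the versions are not given in the sources used here. The authors used DESeq2 for differential expression, per the series' design text. Of 15197 lines in the table, 1 was empty and 9 carried identifiers that name no gene. These 9 took between 0.0206% and 0.0431% of the counts of a library and were left out of library sizes and tests. Of the 15187 named rows, 13511 had at least 1 count, and 15130 were named by an NCBI LOC number.

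The reference table of the assembly GCF_905115235.1 gave gene class and order along the chromosomes for the LOC numbers, but no product names for them. Its coordinates were used only to find which genes are neighbours. The 36 gene lists fixed before the data were examined (detoxification, immunity, digestion, stress response, cuticle, metabolism and tissue markers) relied on product names, so none was formed and no result for them is given. Without product names, the rule for named genes, also fixed before the data were examined, allowed 2 identifiers per direction and comparison. For AFB1 against control at each time, and for the control ages, these were the largest changes among genes with an adjusted p under 0.05 and a mean log2 CPM of at least 1. For the averaged effect and for the difference between times, they were the genes of lowest p. The mitochondrial protein genes, the long non-coding RNA (lncRNA) class and LOC119646963 were chosen after their values were seen. The reads of near-identical or overlapping genes may have been divided between them by the counting, which cannot be judged from the counts.

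Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes with enough counts were kept by filterByExpr over the 6 groups (10165 genes), libraries were scaled by TMM, and 1 negative binomial model with 1 coefficient per group was fitted to all 24 libraries (18 residual degrees of freedom, common biological coefficient of variation 0.513). Differences were tested with the robust quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. CPM values were computed from the deposited counts with the scaled library sizes. A log2 fold change is given with its standard error (SE), which is the size of the change divided by the square root of the F statistic. Where all libraries of a group had 0 counts, the fold was bounded with a floor of 3 counts over the group, from counts summed over the libraries of each group rather than from mean CPM. With 1 to 3 counts in a group, the ratio is given with its exact binomial interval at 95%. Intervals and floors cover counting error only. Gene groups were tested with camera of limma 3.58.1 at its preset correlation, with camera at an estimated correlation and with fry, with adjustment over the 12 tests of a kind.

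The age score of a library was the mean log2 CPM (prior count 2) of up to 250 genes that rose minus that of up to 250 genes that fell between 2 control ages. The genes were chosen on control libraries of the other 2 times, so that no library served for both choice and test. Scores were compared with two-sided exact permutation tests over the 70 divisions of 8 libraries, whose smallest possible p is 0.0286. The overlap of calls between times was tested with Fisher's exact test, two-sided.

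Library totals ran from 6826454 to 27136702 counts. LOC119646963 alone took between 7.12% and 81.1% of them, and the counts left for all other genes ran from 1711314 to 24355059. Counts were simulated with the means, depths and dispersions of the real genes (10100 genes in the fit), without outlying or near-identical libraries. Changed genes were drawn from those with a mean of at least 2 CPM, so genes below it are not covered. Among these, 4-fold changes were recovered in 61.2% of changed genes at 6 h, 44.8% at 24 h and 55.2% at 72 h. For 2-fold changes these shares were 7.46%, 5.97% and 10.4%. Of the simulated genes that were called, 9.09%, 5.56% and 2.88% had not been changed.

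Pairs of libraries of a group were compared by chi-square tests on genes with at least 20 counts. No pair differed by less than sampling noise, and all 24 libraries were kept. Alternatives fixed before the data were examined were DESeq2 1.42.0, RLE scaling, no filter or a filter of 1 CPM in 4 libraries, no robust step, limma voom with quality weights, a replicate block, a fit of only the 8 libraries compared, and leaving out each library. Added after seeing the data were fits without 2 or all of the 8 libraries nearer to another group, without the AFB1 24 h libraries led by 1 gene, with the alike control 72 h libraries summed, without LOC119646963, and with the libraries thinned to 1711314 counts outside LOC119646963. Python 3.11.15 with scipy 1.17.1 was used for the remaining tests.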

Results

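Gene expression was compared between larvae on AFB1 feed and larvae on control feed at 6, 24 and 72 h, with 4 libraries per diet and time. Library totals ran from 7774098 to 17005321 counts in the 12 control libraries and from 6826454 to 27136702 in the 12 AFB1 libraries. In AFB1 24 h libraries they ran from 8143905 to 10745745. The most abundant gene, LOC119646963, took 11.4% ± 3.15 (SD, n = 4) of the counts in control 6 h libraries, 14.8% ± 14.7 in control 24 h libraries and 13.7% ± 1.89 in control 72 h libraries. In AFB1 libraries it took 18.9% ± 12.1 at 6 h, 56.4% ± 25.5 at 24 h and 14.9% ± 8.72 at 72 h. The share reached 74.2% (95% exact binomial interval 74.2 to 74.3%) in AFB1 24 h replicate 3 and 81.1% (81.1 to 81.1%) in replicate 4, which left these libraries 2097793 and 1711314 counts for all other genes.

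**Figure D1:**
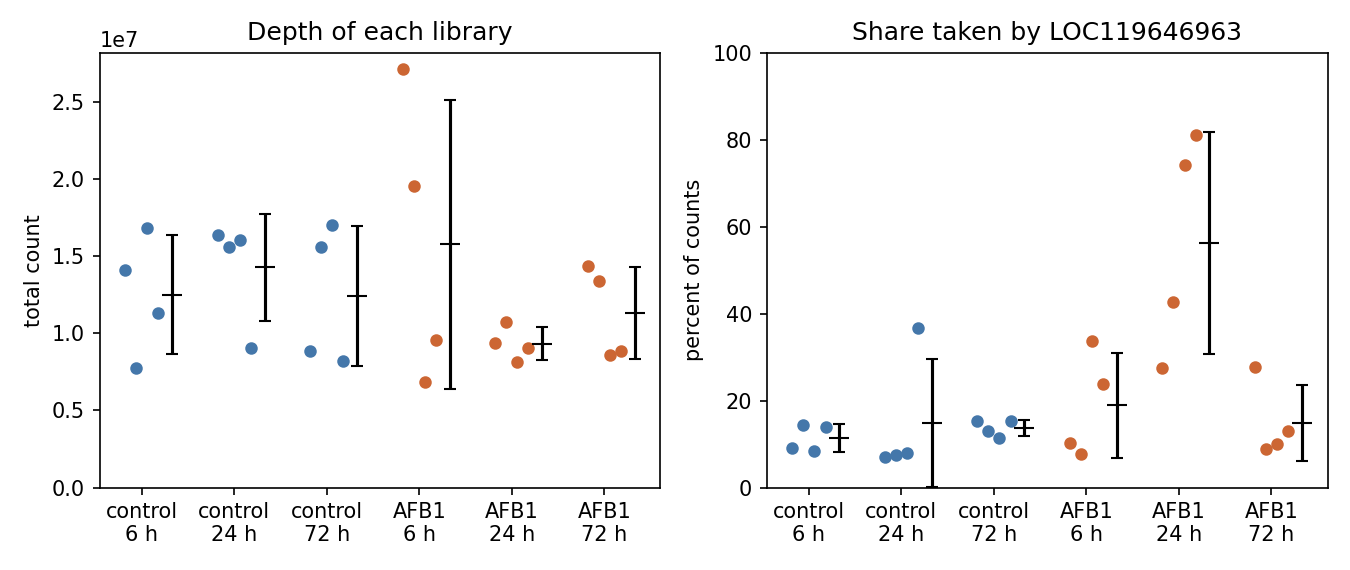
Total count (left) and percent of counts taken by LOC119646963 (right) for each of the 24 libraries, by group. Points are libraries, and the black mark and bar are the mean and SD of 4. The share of LOC119646963 ran from 7.12% to 81.1%, with its highest values in AFB1 24 h libraries.

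The first comparison asked which genes differed after 6 h on AFB1 feed. LOC119651404 fell from 249 ± 98.9 CPM (SD, n = 4) in controls to 0 counts in all 4 AFB1 libraries, at least 5591-fold lower against a floor of 3 counts over the group. LOC119651612 had 1224 ± 1425 CPM in controls, with 9.65 CPM in the lowest and 2948 CPM in the highest library, and 0 counts in the AFB1 libraries, at least 39614-fold lower on counts summed over the group and at least 21765-fold lower without the highest control. Both genes were also low in 24 h controls, at 0.0786 ± 0.0815 and 0.473 ± 0.635 CPM (SD, n = 4). LOC119655013 rose from 5.65 ± 3.30 CPM to 478 ± 771 CPM, with a log2 fold change of 6.39 (SE 1.37), and LOC119646754 rose from 0.925 ± 0.580 CPM to 32.7 ± 28.5 CPM, with a log2 fold change of 5.10 (SE 0.91). The rise of LOC119655013 rests largely on AFB1 replicate 3, at 1631 CPM against 17.5 to 170 CPM in the other 3, and its log2 fold change was 4.04 without it; that of LOC119646754 was 4.37 without AFB1 replicate 4. For each of these 4 genes, the AFB1 and control libraries did not overlap. Their adjusted p-values in edgeR's quasi-likelihood test were 0.000965, 0.00311, 0.00401 and 0.00112, in the order named.

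In total, 1450 of 10165 genes were called at 6 h, of which 663 were higher and 787 lower on AFB1 feed, and 1343 of the called genes changed by at least 2-fold. Of 159 tested lncRNA genes, 8 were higher and 4 lower in edgeR, 19 and 4 in DESeq2 and 3 and 4 in limma voom. The shares called that follow are those of edgeR and were not tested with the other tools. They were also not matched for expression level, so a lower share need not be particular to lncRNA genes. The share called was lower among lncRNA genes (7.55%) than among 9997 protein-coding genes (14.4%; Fisher's exact test, adjusted p = 0.0351 over 3 times), but the 2 shares did not pass that test at 24 h (35.2% against 31.2%, adjusted p = 0.301) or 72 h (5.66% against 9.34%, adjusted p = 0.194). None of the 12 tested mitochondrial protein genes was called in edgeR (3 had an unadjusted p under 0.05) or in limma voom, and 2 were called in DESeq2. *ATP6* and *ND5* were called in edgeR without AFB1 replicate 2 or 4. With only the 8 libraries of 6 h fitted, the number of called genes was 520 (92 higher, 428 lower). In the fit of all groups, the number changed by over 1.5 times without control replicate 2 (942), 3 (817) or 4 (930) or without AFB1 replicate 1 (877), 2 (2207) or 3 (642). The higher genes moved most, to 319, 270, 310, 358, 1076 and 138 in the same order, while the lower genes moved by over 1.5 times without AFB1 replicate 1 (519) or 3 (504). Of the 24 libraries, 8 correlated better with another group than with their own. Without 2 of these (AFB1 6 h replicate 2 and control 24 h replicate 4) the count was 2964 (1474 higher, 1490 lower). It was 567 without all 8 (90 higher, 477 lower) and 824 with the 4 control 72 h libraries summed to 1 (295 higher, 529 lower).

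The same comparison was made at 24 h. LOC119648267 fell from 195 ± 159 CPM (SD, n = 4) in controls to 0 counts in all AFB1 libraries, at least 1045-fold lower, and LOC119649056 fell from 190 ± 90.8 CPM to 0 counts, at least 1271-fold lower. LOC119658527 rose from 0.583 ± 0.877 CPM to 33.5 ± 43.6 CPM, with a log2 fold change of 6.26 (SE 1.57), which was 4.79 without AFB1 replicate 4 (96.8 CPM, against 3.54 to 27.9 in the other 3) and 7.73 without control replicate 4 (1.89 CPM, against at most 0.209). It was 3.46 without AFB1 replicates 3 and 4, where each of these 3 genes lost its call. For these 3 genes the libraries of the 2 diets did not overlap, with adjusted p-values of 0.0066, 0.00763 and 0.00853 in edgeR's quasi-likelihood test. LOC119650202, which the naming rule also gave, had 160 CPM in AFB1 24 h replicate 4 and at most 1.09 CPM in the other 7 libraries. Its log2 fold change of 5.45 (SE 1.77, adjusted p = 0.0254 in edgeR) became -0.79 without that library, and the gene was not called without control replicate 1, 2 or 3 either.

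The transcripts encoded by the mitochondrial genome, which code for subunits of the respiratory chain and the ATP synthase, were among the higher genes. Of 12 tested, 8 rose and none fell, and the median log2 fold change was 2.05. *ND5* rose from 1322 ± 1067 to 19527 ± 18700 CPM, with a log2 fold change of 3.88 (SE 0.79, adjusted p = 0.00513 in edgeR), and *COX1* from 992 ± 920 to 4976 ± 3500.3 CPM, with 2.33 (SE 0.66, adjusted p = 0.014). *ND4*, *ND6*, *COX3*, *ND4L*, *ATP8* and *ND1* also rose. *CYTB* (2.95), *ATP6* (2.19), *ND3* (0.61) and *COX2* (0.10, and -0.13 in limma voom) did not pass. Of the counts outside LOC119646963, these genes made up 4.78% ± 1.11 in controls and 11.8% ± 4.18 in AFB1 libraries (SD, n = 4). The group passed camera (adjusted p = 7.82e-06), did not pass with an estimated correlation (adjusted p = 0.323) and passed fry (adjusted p = 0.00171). LOC119646963 itself rose with a log2 fold change of 3.51 (SE 0.94, adjusted p = 0.011 in edgeR), which was 5.22 without control replicate 4, the library of 525924 CPM against 48788 to 54901 in the other 3 controls, and 1.39 and not called without AFB1 replicates 3 and 4. Of 159 lncRNA genes, 49 rose and 7 fell at 24 h, with a median log2 fold change of 1.08. That class passed camera (adjusted p = 2.00e-05), did not pass with an estimated correlation (adjusted p = 0.323) and passed fry (adjusted p = 0.0282). The summed share of the mitochondrial genes and that of LOC119646963 were highest in AFB1 24 h replicates 3 and 4, though single genes such as *ND3* were not. Leaving out control replicate 4 gave 10 called mitochondrial genes and raised *ND5* to 4.62, *COX1* to 3.22, *COX3* from 1.90 to 2.65 and *ND4* from 2.60 to 3.85, with *CYTB* (5.52) and *ATP6* (4.68) called. The number called was 5 without control replicate 3 and 4 without AFB1 replicate 3, where *COX1* (1.76) was not called. *ND4* was called in neither of these 2 settings, and *ATP8* and *ND1* lost the call without any 1 of 5 libraries of 24 h each. *CYTB* was also called without AFB1 replicate 1. Without AFB1 replicates 3 and 4, no mitochondrial gene was called in edgeR (6 had an unadjusted p under 0.05) and their median log2 fold change was 1.33.

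**Figure D2:**
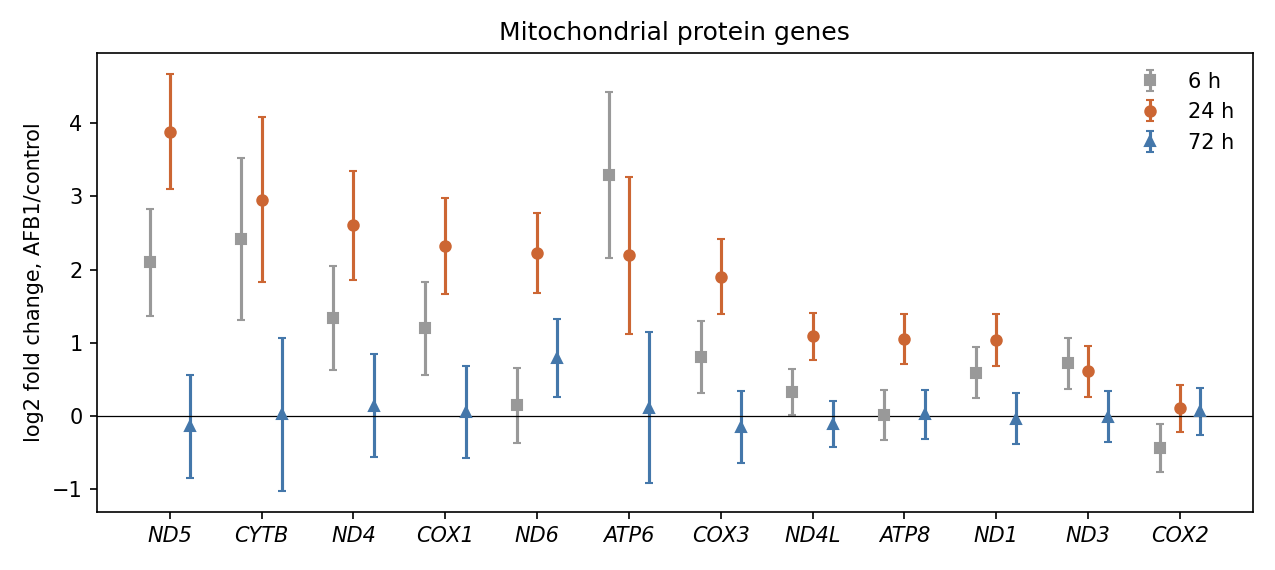
Log2 fold change of AFB1 over control for the 12 tested mitochondrial protein genes at 6, 24 and 72 h. Points are fitted values from 4 libraries per diet and bars are SE. At 24 h the values ran from 0.10 (*COX2*, -0.13 in limma voom) to 3.88 (*ND5*), and 8 of the 12 genes were called in edgeR; none was called in edgeR at 6 h (3 with an unadjusted p under 0.05, 2 called in DESeq2) or 72 h (0 in each).

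Across all genes at 24 h, 3181 were called, 1238 higher and 1943 lower, and the median log2 fold change of all genes was -0.16. The count fell to 1 gene (2889 with an unadjusted p under 0.05 in edgeR) without AFB1 replicates 3 and 4, and was 3224 when control 24 h replicate 4 was left out as well. It was 854 with only the 8 libraries of 24 h, 5917 with limma voom, and 1768, 2017, 1556 and 1674 without control replicate 1, 2 or 3 or AFB1 replicate 3. In these 4 settings the higher genes numbered 610, 666, 532 and 528, and they numbered 2037 without control replicate 4 and 733 without AFB1 replicate 4. The lower genes fell to 1158, 1024 and 1146 without control replicate 1 or 3 or AFB1 replicate 3.

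At 72 h the genes of largest fall were again absent from all AFB1 libraries. LOC119657225 fell from 1430 ± 52.8 CPM (SD, n = 4) to 0 counts, at least 25793-fold lower, and LOC119649344 fell from 364 ± 26.6 CPM to 0 counts, at least 6778-fold lower. LOC119655117 rose from 4.18 ± 0.409 CPM to 961 ± 1082 CPM, with a log2 fold change of 7.84 (SE 1.32) and 40.9 CPM in its lowest AFB1 library; without AFB1 replicate 2 it was 7.01. LOC119650202 had 514 and 532 CPM in 2 AFB1 libraries and 1.44 and 3.22 CPM in the other 2, against 1.05 ± 0.436 CPM in controls, with a log2 fold change of 7.94 (SE 1.95), or 7.34 without AFB1 replicate 3. Adjusted p-values in edgeR's quasi-likelihood test were 0.000761, 0.0019, 0.000468 and 0.00988, in the order named.

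In total, 943 genes were called at 72 h, 341 higher and 602 lower. The higher genes fell to 214, 207, 201 and 206 without control replicate 1, 2, 3 or 4, while no single library moved the lower genes by over 1.5 times. No mitochondrial protein gene was called in edgeR (0 with an unadjusted p under 0.05), DESeq2 or limma voom, and their median log2 fold change in edgeR was 0.02. Of the lncRNA genes, 1 was higher and 8 lower. The 4 control 72 h libraries were far more alike than those of any other group, with 1.87% to 21.3% of genes differing between 2 of them, against 35.9% to 81.9% in the other groups. Replicates 1 and 4 differed at 1.87% of genes and replicates 2 and 3 at 6.43%, against 20.8% to 21.3% across these pairs. Summed to these 2 pairs, the 4 libraries gave 458 called genes (55 higher, 403 lower), and summed to 1 they gave 258, all lower. Limma voom gave 2226 and the fit without the 8 libraries nearer to another group 1587.

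Averaged over the 3 times, the comparison set 12 AFB1 against 12 control libraries. LOC119657298 fell from 626 ± 665 CPM in controls to 0.291 ± 0.553 CPM on AFB1 feed (SD, n = 12), with a log2 fold change of -9.29 (SE 0.72), or -10.68 without AFB1 24 h replicate 1. LOC119648918 fell from 472 ± 511 to 0.147 ± 0.131 CPM (SD, n = 12), with -9.09 (SE 0.72). Both had low values in 24 h controls too, 4.41 ± 3.51 and 2.25 ± 2.19 CPM (SD, n = 4). LOC119651323 rose from 113 ± 69.8 to 308 ± 112 CPM (SD, n = 12), with 1.62 (SE 0.22), and LOC119659847 from 4.57 ± 3.81 to 30.0 ± 20.6 CPM (SD, n = 12), with 2.83 (SE 0.37). Their adjusted p-values were 6.85e-08, 6.85e-08, 9.81e-06 and 9.33e-06 in edgeR's quasi-likelihood test. In all, 3805 genes were called, 1847 higher and 1958 lower, against 2521 and 1173 with the 4 control 72 h libraries summed to 2 and to 1.

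**Figure D3:**
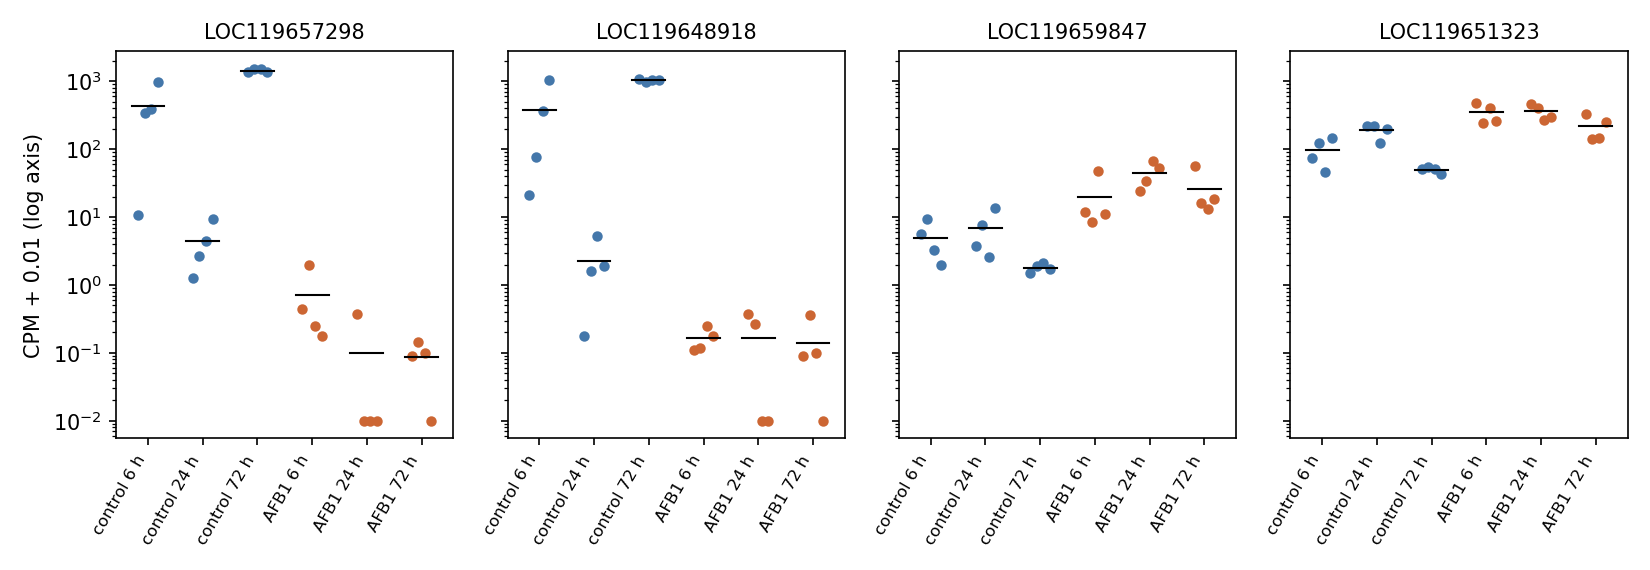
CPM plus 0.01, on a log axis, of the 4 genes named for the effect averaged over times, in each of the 24 libraries. Points are libraries and lines are group means of 4. LOC119657298 and LOC119648918 are low in all AFB1 groups and in 24 h controls, while LOC119659847 and LOC119651323 are higher in AFB1 groups.

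Whether the effect of AFB1 changed with time was tested itself. LOC119647977 had a log2 fold change of 1.01 (SE 0.48) at 6 h, -0.89 (SE 0.48) at 24 h and -6.40 (SE 0.60) at 72 h, where it averaged 1481 ± 120 CPM in controls and 17.6 ± 2.86 CPM in AFB1 libraries (SD, n = 4). LOC119648359 went the same way, with 0.23 (SE 0.75), -2.03 (SE 0.78) and -10.96 (SE 1.14). LOC119655316 was lower on AFB1 feed at 6 h (-7.25, SE 1.10) and higher at 72 h (2.77, SE 0.85), and the difference of 10.02 between these was 8.93 without control 6 h replicate 2 and 10.87 without AFB1 6 h replicate 1. LOC119657798 had -8.02 (SE 1.03) at 6 h, 2.58 (SE 0.99) at 24 h and -1.45 (SE 0.68) at 72 h. At 24 h this gene had only 18 counts over the AFB1 libraries (0 to 6.11 CPM) and 14 over the controls (0.0418 to 0.947 CPM). The libraries of the 2 diets overlapped, so its change of sign at 24 h is weak ground. At 6 h it had 4 counts over the AFB1 libraries. Adjusted p-values of the difference between times were 5.50e-05, 0.000327, 0.0022 and 0.00135 in edgeR. Among the mitochondrial genes, *ND5* came nearest with an adjusted p of 0.0518, so a difference of their response between times was not shown.

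The effect differed between times in 556 genes. By pairs of times, 131 genes differed between 24 and 6 h, 303 between 72 and 6 h and 240 between 72 and 24 h. This count was 12 with the control 72 h libraries summed to 1, 1730 with DESeq2, 2366 without control 24 h replicate 4 and 2325 without the 8 libraries nearer to another group. Without 1 of the other libraries it ran from 229 (without control 72 h replicate 3) to 1380 (without AFB1 24 h replicate 1), and it changed by over 1.5 times for control 6 h replicate 2 (364), control 24 h replicates 1, 2 and 3 (312, 273 and 288), control 72 h replicates 1, 2 and 4 (238, 236 and 240), AFB1 6 h replicates 1 and 3 (368 and 1057), AFB1 24 h replicate 3 (314) and AFB1 72 h replicate 3 (334).

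Genes called lower at 1 time were often lower at another. Between 6 and 72 h, 339 genes were lower at both times where independent lists would share 46.6. Between 24 and 72 h, 340 were shared against 115, and between 6 and 24 h, 302 against 150. Fewer genes were higher at both times, 168 for 6 and 24 h against 80.7, 61 for 24 and 72 h against 41.5 and 33 for 6 and 72 h against 22.2. All 6 overlaps were larger than independent lists give (two-sided Fisher's exact test, highest adjusted p = 0.0247). The libraries compared differ between the times, but all calls came from 1 fit of the 24 libraries. Without control 72 h replicate 3, for example, the 6 h calls fell from 1450 to 1218. Fisher's test also treats genes as independent, though neighbouring genes were often called together, so its p-values may be too small. Small excesses such as 33 against 22.2 are therefore weak ground. The 203 genes lower at all 3 times compare with 11 higher at all 3 times. Across genes, which are not independent replicates, log2 fold changes correlated with Pearson's r of 0.493 for 6 and 24 h, 0.417 for 6 and 72 h and 0.584 for 24 and 72 h, and Spearman's rho was 0.475, 0.311 and 0.370. At an adjusted p under 0.01, the overlap of higher genes did not pass Fisher's exact test for 6 and 24 h (6 genes, 1.70 times the number of independent lists, p = 0.169) or for 24 and 72 h (8 genes, 1.99 times, p = 0.065).

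Control larvae also differed between the times. Each time was sampled as 1 group of controls, so age cannot be told apart from any other difference between these groups. Between 6 and 24 h, LOC119655575 fell from 152 ± 29.1 CPM (SD, n = 4) to 1 count over the 4 libraries of 24 h, a ratio of 11212 (95% exact interval 2012 to 442899), and LOC119651934 fell from 538 ± 564 to 0.0756 ± 0.0535 CPM. LOC119657269 rose from 8.16 ± 4.89 to 189 ± 197 CPM and LOC119660057 from 15.1 ± 6.79 to 271 ± 185 CPM. Adjusted p-values in edgeR's quasi-likelihood test were 0.00238, 0.00243, 0.0138 and 0.0273. In all, 151 genes were higher and 358 lower at 24 h, together 509, against 245 with only these 8 libraries, 240 with the control 72 h libraries summed to 1, 899 with DESeq2 and 1218 with limma voom. It was 339 without control 6 h replicate 2, 281 without control 24 h replicate 2 and 285 without the 8 libraries nearer to another group. The higher genes fell to 46, 91 and 98 without control 6 h replicate 2, 3 or 4 and to 79 and 90 without control 24 h replicate 2 or 4, and the lower genes to 202 and 232 without control 24 h replicate 2 or 3. LOC119660057 was not called without any 1 of the 6 h controls or without control 24 h replicate 2 or 3. The log2 change was 4.54 for LOC119657269 (3.88 without control 24 h replicate 2) and -12.43 for LOC119651934 (-11.43 without control 6 h replicate 1), and without control 24 h replicate 1, LOC119655575 had no count at 24 h.

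From 24 to 72 h, LOC119655575 returned to 165 ± 10.6 CPM (SD, n = 4), a ratio of 12281 (95% exact interval 2204 to 485110). LOC119647298 rose from 0.105 ± 0.108 to 1005 ± 256 CPM, LOC119649197 fell from 186 ± 193 to 0.0943 ± 0.0690 CPM and LOC119647718 from 96.0 ± 110 to 0.139 ± 0.166 CPM. Adjusted p-values in edgeR's quasi-likelihood test were 0.00103, 0.00103, 0.00243 and 0.0134. In all, 623 genes were higher and 538 lower at 72 h, together 1161, against 307 and 78 with the alike control 72 h libraries summed to 2 and to 1, 1751 with only these 8 libraries, 3845 with limma voom and 742 to 760 without 1 of the 4 control 72 h libraries, where the lower genes fell to between 279 and 305. The log2 change was 12.89 for LOC119647298 (13.54 without control 24 h replicate 3), -10.71 for LOC119649197 (-9.75 without control 24 h replicate 1) and -9.33 for LOC119647718 (-8.17 without control 24 h replicate 1, -10.52 without control 72 h replicate 2, and not called without control 72 h replicate 3).

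The rise of LOC119655575 after its fall was shared by many genes. In the fit of all 24 libraries, 303 genes were lower at 24 h than at 6 h and higher again at 72 h, against 21.9 for independent lists, and 107 were higher and then lower, against 7.99. There were 0 genes lower at both steps and 0 higher at both, against 18.9 and 9.25. Every gene called at both steps thus reversed. With the control 72 h libraries summed to 1, no gene was called lower from 24 to 72 h in edgeR. In a fit of the 12 control libraries alone, with 1028 and 1738 genes called at the 2 steps, 479 genes were lower at 24 h than at 6 h and higher again at 72 h, against 51.1 for independent lists, and 269 were higher at 24 h and lower again at 72 h, against 36.5. These steps share the 24 h controls. In 10 simulations of unchanged controls neither step had a call, so they give no measure for these counts. With the 24 h controls split so that the steps share no library, the 6 splits gave between 228 and 314 genes of the first kind and between 69 and 154 of the second. The covariance of the log2 changes across genes was -1.63, against -0.116 in the simulations and a mean of -1.50 with the controls split.

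The age score asked whether AFB1 larvae stood apart from controls of their own time on genes that changed between 2 other control ages. It did not always order the controls by age. On the 24 to 72 h genes, 6 h controls (0.76) lay between 24 h (-4.94) and 72 h controls (2.73). On the 6 to 24 h genes, 72 h controls (-2.17) lay below 6 h controls (-1.91). Only on the 6 to 72 h genes were the ages in order (-1.01, -0.75 and 1.58). A low score at 6 h thus marks likeness to 24 h controls and not an age. At 6 h, on genes that changed between 24 and 72 h in controls, the 4 AFB1 libraries scored -4.79 ± 0.38 (SD, n = 4), between -5.34 and -4.50. The 4 controls of 6 h scored 0.76 ± 1.42, between -0.41 and 2.55, while control 24 h libraries averaged -4.94 and control 72 h libraries 2.73. The difference of -5.55 had the smallest p the two-sided exact permutation test allows (0.0286, adjusted p = 0.0857 over 3 times). At 24 h, on genes that changed between 6 and 72 h, AFB1 libraries scored -0.41 ± 0.27 and controls -0.75 ± 1.13 (exact permutation p = 0.6, n = 4). Control 24 h replicate 4 scored 0.84, against -1.65 to -0.74 in the other controls. Without it the difference was 0.86 rather than 0.34 (exact permutation p = 0.0571). At 72 h, on genes that changed between 6 and 24 h, the AFB1 libraries scored between -2.48 and 2.61 and controls between -2.21 and -2.14 (exact permutation p = 0.143, n = 4).

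**Figure D4:**
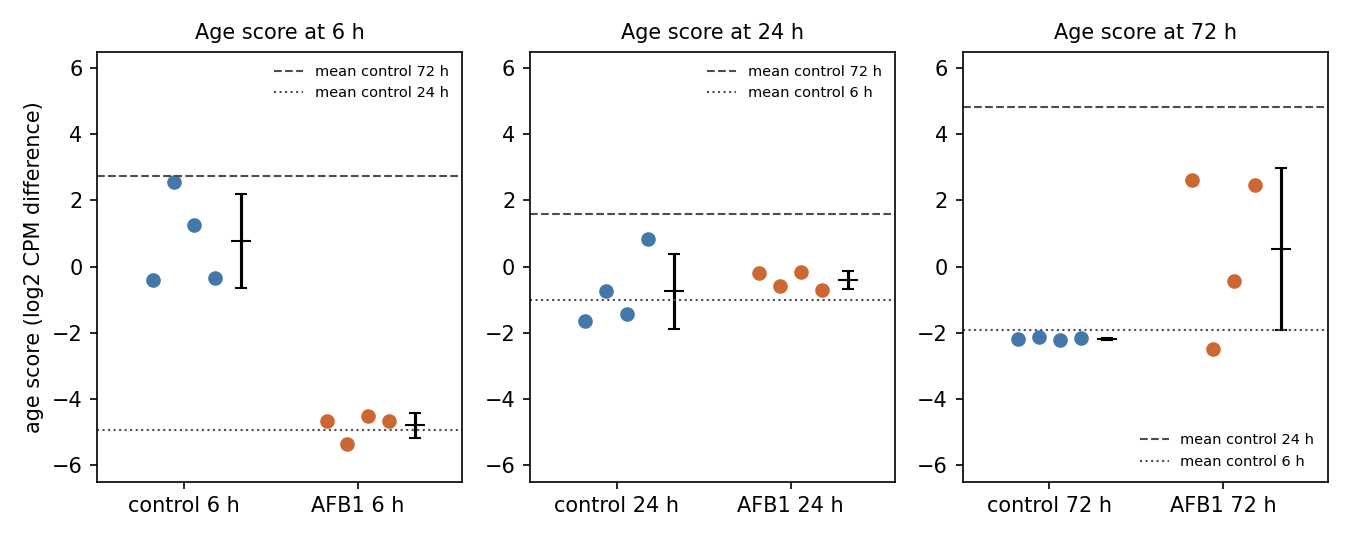
Age score of each library, in log2 CPM, for controls and AFB1 larvae at 6, 24 and 72 h. Points are libraries, black marks and bars the mean and SD of 4, and lines the mean scores of the 2 control groups of other times on which the genes were chosen. At 6 h all AFB1 libraries lie between -5.34 and -4.50, near the mean of 24 h controls, and the 6 h controls lie between -0.41 and 2.55.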

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

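In this part, the tests of explanations were chosen after the results were seen, and the bound for the counts over other splits was written down after those counts were seen; only the comparison of control 72 h pairs at a common depth was written down before its result.

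Of 60 groups of 4 values tested for a library far from the rest, 3 had one, and chance gives about 1 in 20. In control 24 h replicate 4, LOC119646963 took 36.8% of counts against 7.12 to 7.92% in the other 3 libraries, and its counts outside that gene were 5719408 against 14435767 to 15233182. In AFB1 72 h replicate 1, mitochondrial protein genes took 7.57% of counts outside LOC119646963 against 4.71 to 4.96% in the others. The rows that name no gene, which no comparison uses, took up to 0.0431% of a library.

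The fitted effect of AFB1 differed between times in 15 of the named genes, 4 of which were named for that difference. The others were named from the same data, most for a large change at 1 time or between control ages. Their number is therefore no separate evidence of such differences. Over all genes, the effect differed in 556 of 10165 (5.47%). The log2 effect at 72 h minus that at 6 h was 18.10 for LOC119651612, 10.72 for LOC119650202, 6.96 for LOC119655117, 6.58 for LOC119657798, 10.02 for LOC119655316, 13.42 for LOC119655575 and 12.57 for LOC119651934. It was -12.99 for LOC119657225, -12.83 for LOC119649344, -7.40 for LOC119647977, -11.20 for LOC119648359, -4.79 for LOC119657298, -1.23 for LOC119648918, -1.43 for LOC119657269 and -1.76 for LOC119660057, and the test also covers 24 h. Adjusted p-values of the difference in edgeR ran from 5.50e-05 (LOC119647977) to 0.0446 (LOC119657225). Where a group had 0 counts, as for LOC119651612, LOC119657225 and LOC119649344, the fitted size depends on the prior count. LOC119655575 had 1 count over the AFB1 6 h libraries and from 0 to 570 CPM in AFB1 72 h libraries. LOC119651934 had 11 counts and from 0.08 to 1540 CPM in the same groups, so these 2 sizes are also uncertain.

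AFB1 6 h libraries resembled 24 h controls: all 4 correlated best, among the control groups, with the 24 h controls, also at a common depth, with a mean correlation of 0.854 against 0.747 with 6 h controls. AFB1 24 h libraries also correlated best with 24 h controls (mean 0.766, against 0.668 with 6 h and 0.652 with 72 h controls). So did AFB1 72 h replicates 1 and 4 (0.737 and 0.751), while replicates 2 and 3 correlated best with 6 h controls (0.803 and 0.756). The likeness was thus not particular to AFB1 6 h libraries. AFB1 6 h replicate 2 alone does not account for the likeness at 6 h, since the other 3 libraries, set against the other 3 controls of 24 h, also correlated best with that age (3 of 3). An exchange of AFB1 6 h replicate 2 and control 24 h replicate 4 cannot be told apart from true labels for these 2 libraries: the former correlated better with the other 24 h controls (0.954) than with its own group (0.871), but the latter correlated with the other AFB1 6 h libraries only 0.00639 better than with its own group, within the SD of 0.0351, and as well with the AFB1 24 h libraries (0.822, against 0.815 with its own group, and 0.840 against 0.810 at a common depth). This form of the test replaced a first one, which asked only for the group of highest correlation and had pointed to an exchange, and a test of the depth of control 24 h replicate 4 was dropped with it. Such an exchange would bear on these 2 libraries and not on the other 3. The age score at 6 h also placed AFB1 libraries (-4.79) near 24 h controls (-4.94) and apart from 6 h controls (0.76). It measures the same likeness on the same libraries. That AFB1-fed larvae at 6 h were in the state of 24 h controls stays open, since no other test was made of it.

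At 24 h, 8 of the 12 mitochondrial genes and LOC119646963 were called higher in AFB1 libraries, though the libraries of the 2 diets overlapped for 9 of the 12 and for LOC119646963, and the group did not pass camera with an estimated correlation (adjusted p = 0.323). At a common depth the median log2 fold change of the mitochondrial genes was 2.07 with 9 of 12 called. Unequal depth in the fit thus did not make the pattern. Thinning keeps the proportions within each library, so it cannot test a bias that came with the low counts outside LOC119646963 in AFB1 24 h libraries. With the most abundant gene removed the median was 2.02 with 8 called, which argues against a scaling distorted by that gene alone. TMM already sets genes of extreme ratio aside, so little change was likely in advance. A shift of composition over many other genes was not tested. Whether the 2 libraries led by 1 gene alone make the pattern cannot be told apart from a response of all 4: without them the median was 1.33, with values from -0.28 to 2.18 against 0.10 to 3.88 with them, and no gene was called with 2 libraries left, while leaving out control 24 h replicate 4 as well gave 1.81 and 8 called. A response to AFB1 and a difference in the quality of these RNA samples stay open, and the latter was not tested.

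The control 72 h libraries were nearly identical. Low depth hiding differences is argued against, since at a common depth every pair of another group still differed at 21.7% of genes or more and every control 72 h pair at 7.53% or fewer. With all counts, the control 72 h pairs differed at no more than 21.3% of genes and all other pairs at 35.9% or more. The 4 libraries also formed 2 closer pairs. At a common depth, replicates 1 and 4 differed at 0.135% of genes and replicates 2 and 3 at 0.618%, against 6.24% to 7.53% across the pairs. Repeat libraries of the same RNA and pools of larvae that were truly more alike at that time both stay open, since no test apart from the pattern itself was made of either, and the called genes at 72 h fall from 943 to 258 with these libraries summed to 1.

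Other splits of the same libraries were used to ask whether chance can be excluded. For 6 h, 1 of the 35 splits gave as many genes, the real one with 1450, and the highest other split gave 235. The same was seen for control 24 h against 6 h (1 of 35, 509 against 67). A share of 1 in 35 (2.86%) is the smallest these splits can give, and it was not adjusted over the comparisons. Chance is thus less likely for these 2 but not excluded. At 72 h the real division was also alone (1 of 35 splits, 943 against 0), as for control 72 h against 24 h (1 of 35, 1161 against 0). For the averaged effect it was 1 of 100 relabellings (3805 against 2859). These 3 results bear on chance only if the control 72 h libraries are separate pools. Repeats of the same RNA would fall into both arms of other splits. At 24 h, 2 of the 35 splits gave as many genes, 3181 for the real one and 3273 for a split that exchanges control 24 h replicate 4 with AFB1 24 h replicate 1, so chance is not excluded there. For the difference between times, 4 of 100 relabellings gave as many as the real 556, a share under 0.05, but the highest gave 2332, which points to a structure of the samples that was not tested, so that share is weak ground for excluding chance.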

How the results depend on the processing

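The settings that leave out more than 1 library, sum libraries, thin counts or remove LOC119646963 were chosen after seeing the data. RLE scaling, both other filters and the fit without the robust step left every count of called genes within 1.5 times of the value reported. The gene lists could not be formed, so their alternatives were not run. The cause of the changes below was not tested, except that settings with fewer libraries also have fewer residual degrees of freedom.

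Limma voom with quality weights called 5917 genes at 24 h, 2226 at 72 h, 1218 for control 24 h against 6 h, 3845 for control 72 h against 24 h and 3891 for the difference between times. DESeq2 called 899 for control 24 h against 6 h and 1730 for the difference between times. With only the 8 libraries compared, the counts were 520 at 6 h, 854 at 24 h and 1362 at 72 h, so that the order of the 3 times was not that of all libraries, 245 and 1751 for the control comparisons, and 2 mitochondrial genes at 24 h. Without AFB1 6 h replicate 2 and control 24 h replicate 4, they were 2964 at 6 h and 2525 for the difference. Without all 8 libraries that correlated better with another group than with their own, they were 567 at 6 h, 1587 at 72 h, 285 for control 24 h against 6 h and 2325 for the difference. Without AFB1 24 h replicates 3 and 4, they were 1 at 24 h, 274 for the difference and 0 mitochondrial genes, and without control 24 h replicate 4 as well, 2526 at 6 h and 1079 for the difference. With the control 72 h libraries summed to 2, they were 458 at 72 h, 2521 averaged, 337 and 307 for the control comparisons and 30 for the difference. Summed to 1, they were 824 at 6 h, 258 at 72 h, 1173 averaged, 240 and 78 for the control comparisons and 12 for the difference. Thinned to a common depth, 363 genes differed between times. At an adjusted p under 0.01, the overlap of higher genes was 1.70 times that of independent lists for 6 and 24 h and 1.99 times for 24 and 72 h, past the threshold in neither.

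Replicate numbers did not pair the samples. Deviations of same-numbered libraries correlated between -0.22 and 0.22, 3 of 12 pairs exceeded 0.1, and 1 of 12 controls correlated best with its own number. With the number as a replicate block, 741 genes were called at 6 h, 169 for control 24 h against 6 h and 43 for the difference between times.

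Leaving out 1 library at a time gave 642 to 2207 genes at 6 h, 1556 to 4548 at 24 h, 712 to 1084 at 72 h, 2989 to 4847 averaged, 229 to 2366 for the difference, 281 to 609 for control 24 h against 6 h, 742 to 1305 for control 72 h against 24 h, and 4 (without AFB1 24 h replicate 3) to 10 mitochondrial genes at 24 h. The age score difference ran from -5.94 to -4.95 at 6 h, from 0.04 to 0.86 at 24 h and from 2.02 to 3.72 at 72 h, where 3 against 4 libraries cannot reach p under 0.05. At 6 h the difference was -8.02 with 50 genes per direction and -3.45 with 873 higher and 874 lower genes, and its p was the smallest the test can give in each setting with all libraries, so p says nothing about stability there.

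Of the named genes with a call, 1 reversed: LOC119650202 at 24 h had a log2 fold change of -0.79 without AFB1 24 h replicate 4 (5.87 without replicate 1, the highest with 1 library left out), -0.53 without replicates 3 and 4, and -0.58 without control 24 h replicate 4 in addition. Over the named genes and the other settings, 982 values kept their side of the threshold, 46 lost the call and 27 gained one. Leaving out 1 library, 761 kept their side, 23 lost the call and 7 gained one. A change of sign in a value that was not called counted as kept. At 72 h without AFB1 72 h replicate 1, *COX1* went from 0.05 to -0.56, *CYTB* from 0.02 to -0.98 and LOC119646963 from 0.24 to -0.49. Of simulated 2-fold changes, 7.46% were recovered at 6 h, 5.97% at 24 h and 10.4% at 72 h.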

Other observations

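In this part, the count of genes present on one diet alone, and its comparison with controls of other times, were chosen after the results were seen, and the test of neighbouring genes was written down for 24 h before its result and applied to 6 and 72 h as well.

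Genes absent from the AFB1 libraries of a time but not its controls were more frequent than the opposite. At a common depth of 1711314 counts outside LOC119646963, 38 genes at 6 h, 20 at 24 h and 48 at 72 h had at least 10 counts in each of the 4 controls and 0 in each of the 4 AFB1 libraries. No gene showed the opposite at any of the 3 times. At 72 h the 4 controls were nearly identical, with pairs differing at 7.53% of genes or fewer at this depth. There they add little beyond 1 library, so the 48 genes are weaker ground. Of the 38 genes of 6 h, 29 had under 10 counts in every 24 h control too, as had 7 of the 48 genes of 72 h, so low counts were not particular to AFB1 feed for these, while 1 of the 38 and 1 of the 20 genes of 24 h were as low in every 72 h control. Other splits of the same 8 libraries gave at most 7 genes of either kind at 6 h and 0 at 24 h. They also gave 0 at 72 h, but nearly identical controls then fall on both sides of a split, so that value is no measure.

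Genes that changed together were often neighbours on the chromosomes, which may reflect gene clusters under common control. The hypothesis was that genes next to each other change together, tested on 7855 adjacent pairs of tested protein-coding genes against 1000 shuffles of the calls. At 24 h, 579 pairs were called in the same direction, 1.43 times the mean of the shuffles (406, highest 468). At 6 h there were 187 pairs against a mean of 81.4 (highest 115), and at 72 h 187 pairs against 36.7 (highest 56), where 152 of the pairs were lower on AFB1 feed. The permutation p of 0.001 at each time is the smallest these shuffles can give. The longest run of adjacent genes lower on AFB1 feed held 12 genes at 6 h, 14 at 24 h and 18 at 72 h. Reads shared between near-identical neighbouring copies would also give such pairs and were not tested.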
